A study of Homo sapiens with 6 samples.

How the data were processed

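RNA sequencing of total RNA from HUES8 human embryonic stem cells was analysed from the deposited table of gene counts. It holds whole-number read counts for 63677 Ensembl genes in 6 libraries, 3 of WT cells and 3 of TADA2B KO cells, each in a column of its own that carries the sample's title. The submitters' processing notes name STAR 2.6.1d, Picard, featureCounts 1.6.4 and the human genome build hg19, without roles. The counts were deposited by the authors without normalization, as the different totals per column show (17342606 to 25538162). The strand setting, the treatment of reads that map to several places and the removal of duplicates are not given in the sources used here, so reads of overlapping genes, antisense partners and close paralogs such as the protocadherin clusters are not told apart with certainty. RNA was purified with a column kit, per the labels' protocols, and the labels name no selection of polyadenylated RNA or removal of rRNA.

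Samples were grouped by the genotype in their labels. The replicate numbers 1 to 3 recur in both genotypes, but no label ties a number to a culture, clone or day. The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

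Counts were scaled with TMM factors and filtered with filterByExpr by group in edgeR 4.0.16 (R 4.3.3), which left 16493 genes. The genotypes were compared with edgeR's quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as CPM (edgeR's cpm function with TMM-scaled library sizes), as mean ± SD over the 3 libraries of a group. Standard errors of log2 fold changes (KO less WT) were taken as the size of the fold change divided by the square root of F. Chromosome names, gene order and GC content (from the longest transcript) came from GENCODE 29, which is on another build than the counts, so no coordinate is given; 52526 of the gene identifiers matched it, and 98% of the tested genes had a GC value. Y-linked genes and XIST were not named, and the Y chromosome was left out of the chromosome medians. They were not removed from the fits, the library totals or the counts of genes.

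Gene lists of pluripotency, germ layers, other cell types, chromatin complexes, adhesion, growth, metabolism, stress and signalling (44 lists, 1131 memberships, of which 1128 were found in the table) were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. Camera asks whether a list's genes lie higher or lower than other genes; fry asks whether they move at all. Chromosome medians were tested with 10000 permutations of the genes' chromosome labels. These take genes as the units and do not measure the spread between libraries.

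The rule for named genes was TADA2B, then the 12 genes with the largest positive and the 12 with the largest negative fold change among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, then up to 4 members of each list with the smallest p, and always POU5F1, SOX2 and NANOG. No gene passed the threshold, so that part named none. In its place the same ranking was applied to genes with an unadjusted p under 0.05, and further genes near the threshold, list members shown as examples of a difference between KO libraries, and 5 neighbouring genes were named; these were chosen after their values were seen. Some genes that the rule or these choices would name are not reported here.

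The comparison was repeated with DESeq2 1.42.0, limma-voom, median-ratio and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, an adjusted p of 0.01, each library left out in turn, and for chromosomes a mean of at least 5 CPM and the removal of called genes. Added after the data were seen were leaving out both libraries numbered 1, leaving out the mitochondrially encoded genes, and a correction of each library by a smooth trend (loess, span 0.5) on gene GC content.

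The edgeR and DESeq2 fits were tested on simulated data: 5 sets of counts were drawn for the 16493 genes from the observed means, library sizes and spread, with 200 genes changed. Of the genes changed by 1 on the log2 scale edgeR called 5.2%, of those changed by 2 it called 74.8%, of those changed by 3 it called 96.4%, and of those changed by 5 it called 100%. DESeq2 called 27.6%, 91.6%, 99.2% and 100%. Unchanged genes made up 5.93% of edgeR's calls and 25.3% of DESeq2's. A list of 15 genes higher by 1.5 on the log2 scale was called in 5 of 5 sets, an unchanged list in 0, and a simulated shift of -0.2 on 1 chromosome was returned as -0.20. Each gene was drawn on its own, so these sets do not test list calls where members move together. In the data the estimated correlation was 0.80 for the epithelial to mesenchymal transition list and 0.94 for mitochondrially encoded mRNAs. No simulated library was made to stand apart from its group, as KO replicate 1 does below. In the data edgeR called 0 genes, also where the estimate was 4.13 (BMP4) or 9.11 (ANKRD1). The simulated rates therefore do not carry over to the data, and the count of 0 does not exclude large changes.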

Results

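RNA was sequenced from HUES8, an established human embryonic stem cell line, kept in E8, a defined culture medium for pluripotent cells. The 6 libraries came from unedited cells (WT, 3 libraries) and from cells in which TADA2B had been knocked out (KO, 3 libraries). TADA2B is an adaptor subunit of the histone acetyltransferase module of SAGA, a coactivator complex of RNA polymerase II transcription. The series belongs to CRISPR screens that set the identity of pluripotent cells apart from their fitness, and the comparison asks which genes differ in expression when TADA2B is lost. The WT libraries held 17342606, 20538960 and 19070030 gene-assigned reads and the KO libraries 19796350, 25538162 and 20728950. Reads were found for 24310 to 26171 genes per library, and 16493 genes passed the expression filter. No label says that the replicates came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

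TADA2B mRNA did not separate the genotypes. It stood at 14.3, 11.2 and 13.7 CPM (counts scaled to library size) in the WT libraries and at 10, 14.6 and 11.6 CPM in the KO libraries, means of 13.1 ± 1.69 and 12.1 ± 2.34 CPM (SD, n = 3 each). The log2 fold change was -0.11 with a standard error of 0.27 (edgeR adjusted p = 0.88), and it was 0.0066 without KO replicate 1. Counts over the whole gene neither bear out nor contradict the labels, since small insertions or deletions can end a protein and leave its mRNA in place.

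In all 3 KO libraries BMP4, the cadherin CDH6 and the laminin subunit LAMB1 stood above every WT library, and DNMT3B, PHC1, PYCR1 and RIMS4 stood below; these are single genes, most of them chosen after their values were seen, and not a statement on their families. The mesenchymal genes VIM, CDH2 and TNC were high in KO replicates 2 and 3 and below every WT library in KO replicate 1. No single gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test over all 6 libraries: 0 genes were called, with 2356 genes at an unadjusted p under 0.05, of which 1302 were higher and 1054 lower in KO, where chance alone gives about 825. Other splits of the same libraries into 3 and 3 gave 72 to 2624 such genes, so the excess over 825 does not by itself show an effect of genotype. The smallest adjusted p was 0.077, for SYT3. DESeq2 called 794 genes on the same counts, limma-voom called 1, and edgeR without KO replicate 1 called 1017 genes, 588 higher and 429 lower. The groups did not overlap in 3646 genes, 22.1% of those tested, where chance gives 10%. Genes can move together, so neither 825 nor 10% tells how far such counts scatter by chance.

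KO replicate 1 stood apart from both other KO libraries. Mitochondrially encoded genes took 29.4% of its reads, against 10.8% and 10.4% in KO replicates 2 and 3 and 14.2%, 9.71% and 8.30% in the WT libraries. Over the 11553 genes with a mean of at least 5 CPM, the rank correlation across genes was 0.83 between KO replicates 1 and 2, 0.88 between KO replicates 1 and 3, and 0.96 between KO replicates 2 and 3; genes are not independent replicates. KO replicate 1 lay nearer to each WT library (root mean square difference in log2 CPM of 0.85, 0.76 and 0.87) than to KO replicates 2 and 3 (1.13 and 0.90). Within WT, replicate 1 correlated at 0.94 and 0.92 with replicates 2 and 3, which correlated at 0.99 with each other. Every pair of libraries differed by more than sampling noise, so none repeats the reads of another. Of the 937 genes called without KO replicate 1 that were also tested over all 6 libraries, 613 (65.4%) lay on the same side of the WT mean in KO replicate 1. The same WT libraries served to call these genes and as the reference, which alone pulls KO replicate 1 towards that side. The share without any change was not computed. The 513 higher genes had a median log2 difference from WT of 0.30 in KO replicate 1 against 1.90 over the mean of KO replicates 2 and 3, and the 424 lower ones -0.45 against -2.14.

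Genes that lay on the same side of WT in all 3 KO libraries included those nearest to the threshold; the genes of this paragraph were chosen after their values were seen. BMP4, a signalling ligand that drives pluripotent cells towards mesoderm and extraembryonic fates, had 62.9 ± 36.6 CPM in KO and 3.59 ± 0.57 CPM in WT (SD, n = 3), a log2 fold change of 4.13 ± 0.48 (SE; edgeR adjusted p = 0.11). CDH6, a cadherin, had 35.7 ± 30.5 CPM in KO and 1.54 ± 0.23 CPM in WT. The laminin subunit LAMB1 had 247 ± 119 CPM against 58.4 ± 20 CPM. LIMCH1, an activator of non-muscle myosin, had 61.3 ± 21.7 CPM against 9.59 ± 1.59 CPM, and the secreted protein gene OLFML3 had 369 ± 83.8 CPM against 74.7 ± 19 CPM. PCDH18 had 128 ± 38.2 CPM against 45.4 ± 2.02 CPM, and the lysophosphatidic acid receptor gene LPAR6 had 14.2 ± 3.03 CPM against 1.80 ± 0.55 CPM. In the other direction, PYCR1, an enzyme of proline synthesis, had 36.6 ± 5.70 CPM in KO and 108 ± 6.80 CPM in WT, a log2 fold change of -1.56 ± 0.19 (SE; edgeR adjusted p = 0.11). ANKRD13B had 3.29 ± 0.29 CPM against 16.3 ± 3.35 CPM. For these genes the edgeR adjusted p lay between 0.11 and 0.18, so none was called over all 6 libraries, and each was called by DESeq2 and by edgeR without KO replicate 1.

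**Figure D1:**
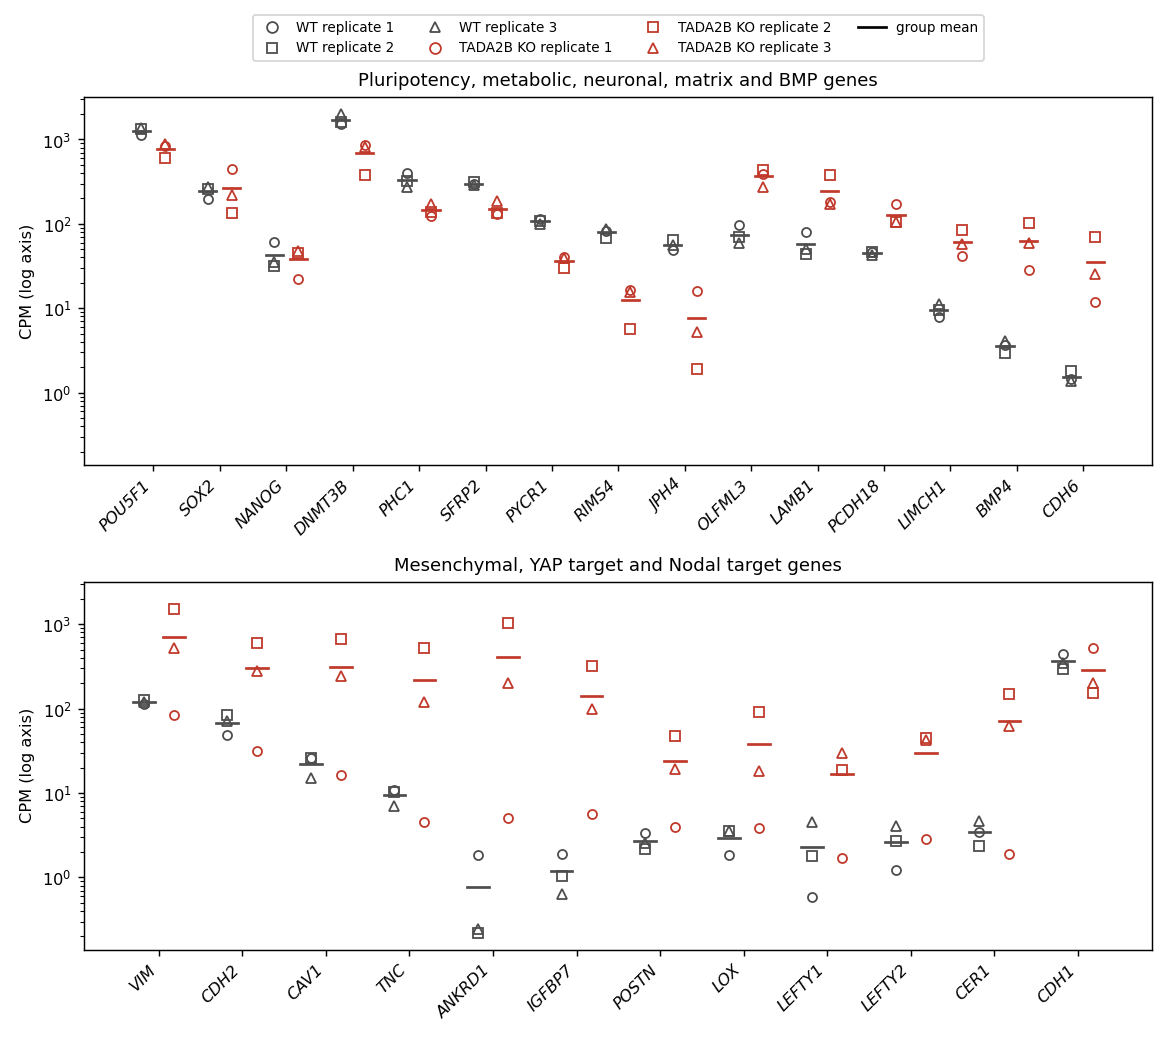
CPM (log axis) of named genes in each library, WT in grey and TADA2B KO in red, with a symbol per replicate number and a bar at each group mean. In the upper panel BMP4 and CDH6 lie above WT in all 3 KO libraries, while in the lower panel VIM and TNC are high in KO replicates 2 and 3 and below the lowest WT library in KO replicate 1.

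The core factors of pluripotency did not move as 1 group. POU5F1 (OCT4) had 774 ± 151 CPM in KO and 1277 ± 128 CPM in WT, a log2 fold change of -0.72 ± 0.23 (SE; edgeR adjusted p = 0.26), with all 3 KO libraries below all 3 WT libraries. SOX2 had 445, 134 and 217 CPM in KO replicates 1 to 3 and 245 ± 40.7 CPM in WT, and NANOG had 38.4 ± 14.2 CPM against 42.8 ± 16.2 CPM. For both the sign of the fold change turned when KO replicate 1 was left out, to -0.48 for SOX2 and 0.13 for NANOG. DNMT3B, the de novo DNA methyltransferase of primed cells, had 688 ± 266 CPM in KO and 1723 ± 260 CPM in WT, and the Polycomb gene PHC1 had 145 ± 25 CPM against 334 ± 63.7 CPM. SFRP2, ZIC2 and TERT had log2 fold changes of -0.99 ± 0.21, -1.31 ± 0.31 and -1.58 ± 0.40 (SE). Of the 36 tested members of the core and primed pluripotency list, 24 lay below 0 and 12 above. None was called over all genes, and 5 lower members and 1 higher one, LEFTY2, passed when adjusted over the list alone. The list was called lower by camera (median log2 fold change -0.37, adjusted p = 0.0019), a call lost with an estimated correlation (adjusted p = 0.82). Its members changed in either direction by fry's mixed test (adjusted p = 0.0054). The naive pluripotency list was not called (adjusted p = 0.65 by camera); its member IL6ST had a log2 fold change of 1.31 ± 0.25 (SE).

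BMP targets were called higher in KO, with 10 of 12 tested members above 0 (median 0.87; camera adjusted p = 0.0019, and adjusted p = 0.82 with an estimated correlation). ID4, an inhibitor of differentiation induced by BMP signals, had 64.4, 15.1 and 21.7 CPM in KO replicates 1 to 3 and 4.72 ± 1.09 CPM in WT (log2 fold change 2.83, and 1.96 without KO replicate 1), and ID2 had 25.3 ± 2.81 CPM against 12.3 ± 3.23 CPM. GATA3 had 0.58, 12.6 and 7.73 CPM in the KO libraries and 0.29 ± 0.09 CPM in WT. These 3 genes passed when adjusted over the list alone. Targets of Nodal, the activin-type signal of the primitive streak, differed between KO libraries. LEFTY1 had 1.69, 18.8 and 29.8 CPM in KO replicates 1 to 3 and 2.30 ± 2.01 CPM in WT, LEFTY2 had 2.85, 44.8 and 42.0 CPM against 2.64 ± 1.40 CPM, and CER1 had 1.92, 151 and 61.5 CPM against 3.47 ± 1.17 CPM. The Nodal and activin list was not called (median 0.65, camera adjusted p = 0.11), nor were mesendoderm (median 1.24, adjusted p = 0.056) or mesoderm (median 0.94, adjusted p = 0.22). Definitive endoderm was called higher over 8 tested members (median 1.51, camera adjusted p = 0.047), a call lost with an estimated correlation (adjusted p = 0.82), without WT replicate 1 (adjusted p = 0.11) and without KO replicate 2 (adjusted p = 0.080). Its median against the WT mean was -0.55 in KO replicate 1, 2.12 in KO replicate 2 and 1.30 in KO replicate 3. Neuroectoderm and neural crest were not called (camera adjusted p = 0.75 for each), although POU3F1, a neuroectodermal POU factor, had 2.87 ± 1.74 CPM in KO and 13.6 ± 0.57 CPM in WT.

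Genes of the epithelial to mesenchymal transition, the extracellular matrix and YAP signalling were called higher as lists. KO replicates 2 and 3 carried the difference, while the median of each list lay below the WT mean in KO replicate 1. Of the transition list, 21 of 23 tested members lay above 0 (median 1.82, camera adjusted p = 0.00028; adjusted p = 0.82 with an estimated correlation), yet its median against the WT mean was -0.67 in KO replicate 1, 2.28 in KO replicate 2 and 1.1 in KO replicate 3. Without KO replicate 2 its median was 0.55 and the call was lost (adjusted p = 0.082). YAP and TAZ targets had a median of 0.98 (18 of 20 above 0, adjusted p = 0.00013 by camera and 0.82 with an estimated correlation), with per-library medians of -0.28, 1.68 and 0.82 in the KO libraries. Extracellular matrix genes had a median of 0.69 (25 of 35 above 0, camera adjusted p = 0.0027; adjusted p = 0.82 with an estimated correlation) and 3 higher and 2 lower members when adjusted over the list alone. Their per-library medians were -0.18, 0.83 and 0.39 in KO replicates 1 to 3. The intermediate filament gene VIM had 85.0, 1523 and 523 CPM in KO replicates 1 to 3 and 120 ± 7.18 CPM in WT, and N-cadherin (CDH2) had 31.6, 608 and 279 CPM against 68.4 ± 18.2 CPM. TNC had 4.54, 529 and 121 CPM against 9.47 ± 2.06 CPM. ANKRD1, a YAP target, had 5.01, 1024 and 202 CPM against 0.77 ± 0.94 CPM. E-cadherin (CDH1) had 517, 152 and 203 CPM in the KO libraries against 362 ± 76.0 CPM. Protocadherins were called higher (23 of 27 above 0, median 0.77, camera adjusted p = 0.0079; adjusted p = 0.82 with an estimated correlation). Their per-library medians overlapped between the groups, at 0.550, 0.339 and 0.090 in KO replicates 1 to 3 and 0.345, -0.223 and -0.075 in WT replicates 1 to 3. Markers of fibroblasts, which do not belong to a pluripotent culture, had a median of 1.03 (camera adjusted p = 0.056), with POSTN at 3.96, 47.8 and 19.4 CPM in the KO libraries and 2.71 ± 0.60 CPM in WT, and 6 higher members when adjusted over the list alone. Integrins and focal adhesion genes had a median of 0.28 (adjusted p = 0.083), with ITGAV at 258 ± 188 CPM in KO and 64.8 ± 11.7 CPM in WT. Cadherin and junction genes were not called as a list (median 0.16, adjusted p = 0.50).

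**Figure D2:**
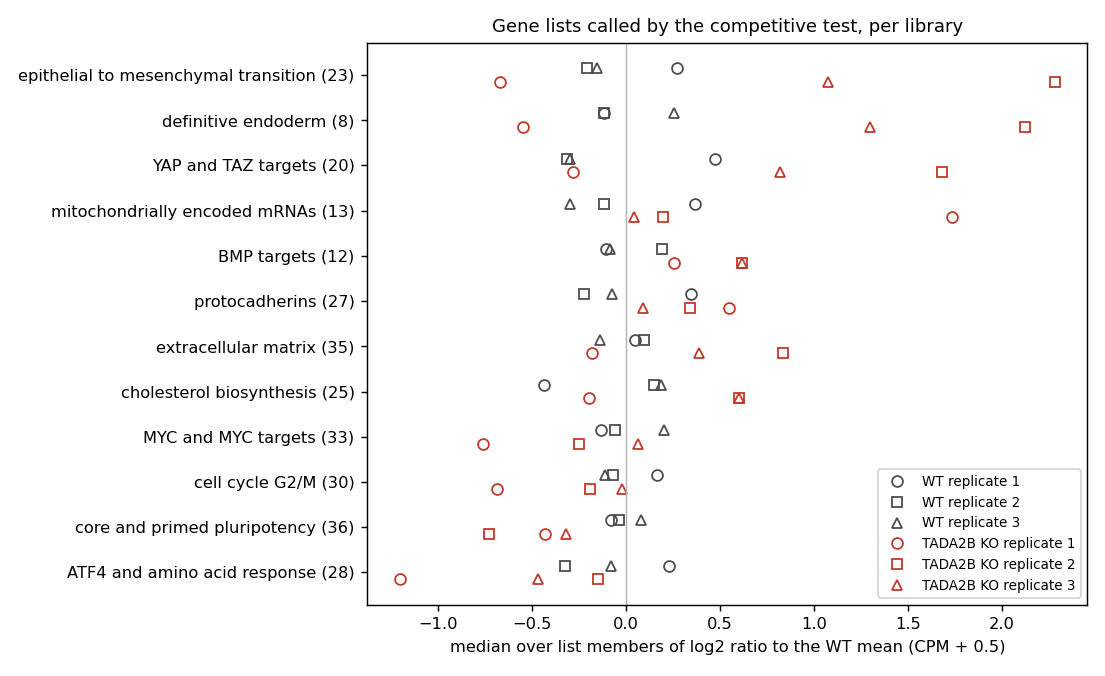
Median over the tested members (number in brackets) of the log2 ratio of each library to the WT mean, for the 12 gene lists called by camera; WT libraries are grey, TADA2B KO libraries red. The KO libraries lie on 1 side of 0 in 6 lists, among them BMP targets and core pluripotency, while the transition list runs from -0.67 to 2.28. Of these 6 lists, BMP targets and core pluripotency alone have every KO library beyond all WT libraries.

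The ATF4, MYC, G2/M and mitochondrially encoded lists leaned on KO replicate 1, the library with the high mitochondrial share. The ATF4 and amino acid response list was called lower (23 of 28 members below 0, median -0.58, camera adjusted p = 0.00028; adjusted p = 0.82 with an estimated correlation), with per-library medians of -1.2, -0.15 and -0.47 in the KO libraries. PHGDH, the first enzyme of serine synthesis, had 263 ± 45.8 CPM in KO and 519 ± 14.2 CPM in WT, lower in each KO library, and was the 1 member that passed when adjusted over the list alone. MYC and its targets (27 of 33 below 0, median -0.21) and G2/M genes (25 of 30 below 0, median -0.28) were called lower with adjusted p = 0.0027 and 0.026 by camera, and with adjusted p = 0.82 and 0.83 with an estimated correlation. MYCN had 43.4 ± 18.8 CPM in KO and 104 ± 30.3 CPM in WT. Mitochondrially encoded mRNAs were called higher (13 of 13 above 0, median 0.91, camera adjusted p = 0.00091; adjusted p = 0.82 with an estimated correlation), with a median of 1.73 in KO replicate 1 against 0.20 and 0.04 in KO replicates 2 and 3. Without KO replicate 1 the calls of all 4 of these lists were lost, with camera adjusted p = 0.32 for the ATF4 list, 0.49 for MYC targets, 0.77 for G2/M and 0.44 for mitochondrially encoded mRNAs. G2/M was also lost without WT replicate 1 (adjusted p = 0.15) and MYC targets without WT replicate 3 (adjusted p = 0.084). Cholesterol biosynthesis was called higher (23 of 25 above 0, median 0.47, camera adjusted p = 0.00028; adjusted p = 0.82 with an estimated correlation), with per-library medians of -0.20 in KO replicate 1 and 0.60 in each of KO replicates 2 and 3. Its genes MSMO1, SC5D, INSIG1 and STARD4 had log2 fold changes of 0.95 ± 0.22, 1.19 ± 0.28, 0.70 ± 0.19 and 0.84 ± 0.23 (SE) and passed when adjusted over the list alone. Glycolysis (median -0.17, adjusted p = 0.12), nuclear-encoded oxidative phosphorylation (0.01, 0.86), ribosomal proteins (-0.02, 0.36) and p53 targets (-0.08, 0.97) were not called by camera.

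The other subunits of the complexes that hold TADA2B or its paralog did not shift as groups. SAGA genes had a median log2 fold change of 0.07 over 25 members (camera adjusted p = 0.75), and genes of ATAC, a related acetyltransferase complex, had -0.07 over 13 members (adjusted p = 0.87), with a mean of 0.10 of the opposite sign. KAT2B, an acetyltransferase of both, had 3.88 ± 1.59 CPM in KO and 1.26 ± 0.78 CPM in WT (log2 fold change 1.63 ± 0.60, SE). Histone acetyltransferases and deacetylases (-0.12), Polycomb and trithorax genes (0.02) and TFIID subunits (-0.04) were not called (camera adjusted p = 0.60, 0.77 and 0.50). Across the 44 lists, 12 were called by camera, 8 higher and 4 lower. None of the 12 was kept with an estimated correlation, and fry called 0 lists (smallest adjusted p = 0.10) for a shift in 1 direction and 2, core and primed pluripotency and BMP targets, for change in either direction. Adjusted over the list alone, 39 memberships passed with higher and 11 with lower expression, in 20 lists; over all genes tested, 0 passed.

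Genes with a mean of at least 5 CPM, no overlap between groups and an unadjusted p under 0.05 were ranked by the size of the difference, a ranking chosen after the values were seen; genes of lower level, such as those on chromosome 19 below, are not in it. Among the 12 highest, IGFBP7 had 5.59, 317 and 98.3 CPM in KO replicates 1 to 3 and 1.2 ± 0.65 CPM in WT. MFAP5, ZEB2, CDKN2A, LIX1, EDN1, PDE1C, FLI1, LCP1, FAM20A and TRPC6 had log2 fold changes between 4.74 for TRPC6 and 6.78 for MFAP5, and ANKRD1 reached 9.11 ± 1.98 (SE). FAM20A and TRPC6 were highest in KO replicate 1, at 43.8 and 22.3 CPM, and without it their log2 fold changes were 2.73 and 3.59, while the rest were highest in KO replicate 2. Some of the rest were near the WT level in KO replicate 1. ZEB2, FLI1 and PDE1C had 10, 11 and 12 reads there, against up to 8, 10 and 11 in a WT library. Among the 12 lowest, several genes are best known from neurons or neuroendocrine cells. The presynaptic gene RIMS4 had 12.5 ± 5.96 CPM in KO and 79.1 ± 9.76 CPM in WT. The junctophilin JPH4 had 7.73 ± 7.40 CPM against 56.6 ± 7.56 CPM, chromogranin A (CHGA) 3.55 ± 1.73 CPM against 27.6 ± 16.6 CPM, and the pentraxin NPTX2 3.62 ± 1.92 CPM against 27.1 ± 12.3 CPM. NRXN2 and DPYSL5 had log2 fold changes of -2.98 ± 0.61 and -2.81 ± 0.36 (SE). The rest were TMEM151B, MYH14, MMP17, ZNF521, SNAI3 and CORO1A, between -2.42 for CORO1A and -3.22 for TMEM151B. None of these 24 genes was called by edgeR over all 6 libraries (adjusted p of 0.11 or more).

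On chromosome 19, 5 neighbouring genes were near 0 in all 3 KO libraries. LRRC4B had 129, 138 and 86 reads in the WT libraries and 2, 0 and 1 in the KO libraries. SYT3 had 123, 196 and 194 reads against 0, 2 and 1, and CLEC11A had 41, 108 and 38 against 0, 1 and 1. C19orf81 had 23, 29 and 18 reads in WT and SHANK1 22, 20 and 17, and neither had a read in KO. Scaled to library size, the KO level was 0.82% of WT for LRRC4B (95% exact interval 0.17% to 2.41%), 0.56% for SYT3 (0.12% to 1.66%) and 1.03% for CLEC11A (0.12% to 3.78%). C19orf81 was 24.2-fold lower and SHANK1 20.4-fold lower when 3 reads over the KO group were taken as the floor. Their exact 95% intervals reach further, up to 5.22% and 6.22% of WT. Intervals and floors cover counting error only. The genes on either side were read in KO, JOSD2 at 99.2% (60.1% to 164%) and EMC10 beyond it at 117% (113% to 122%) of WT, and C19orf48 at 75.2% (72.3% to 78.1%). Farther out the neighbourhood was lower too, with MYH14 at 10.3% (9.15% to 11.6%) and a median log2 fold change of -0.66, less that of all genes, over the nearest 20 tested genes. The edgeR adjusted p of the 5 genes lay between 0.077 and 0.16. These 5 genes were named after their values were seen.

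**Figure D3:**
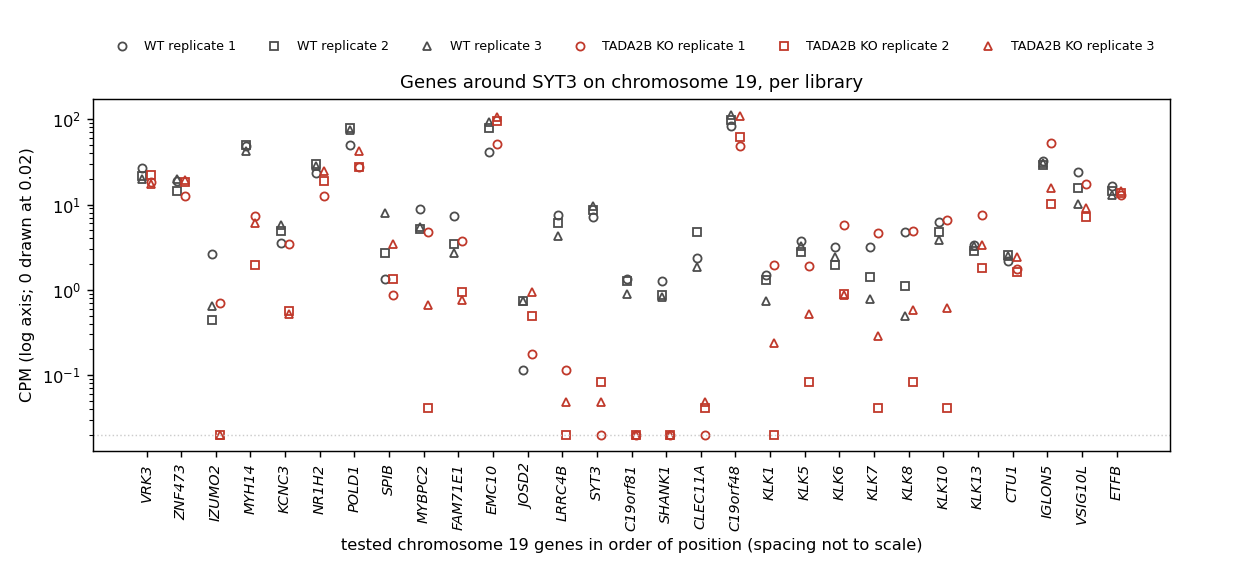
CPM (log axis, values of 0 drawn at 0.02) of tested chromosome 19 genes in order of position, WT in grey and TADA2B KO in red. LRRC4B, SYT3, C19orf81, SHANK1 and CLEC11A are at or near 0 in all 3 KO libraries, and EMC10 and C19orf48 near them are not.

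Whole chromosomes shifted by small amounts. The median log2 fold change of a chromosome's genes, less that of all genes, passed a permutation of the chromosome labels (adjusted p under 0.05 over 23 chromosomes) for 15 chromosomes, 5 lower and 10 higher. The lower ones were chromosomes 19 (-0.35), 22 (-0.23), 20 (-0.21), 16 (-0.19) and 17 (-0.11), each at p = 1e-04, the smallest that 10000 permutations can give, and the largest higher shift was 0.17 on chromosome 13. The shift followed the median GC content of the chromosome's genes across the 23 chromosomes (Pearson's r = -0.94 and Spearman's rho = -0.94, each with permutation p = 1e-05, the smallest possible; r = -0.89 without the 2 chromosomes farthest from the median). After a GC correction of each library, chosen after the data were seen, 5 chromosomes passed: 19 (-0.13), 20 (-0.18), 16 (-0.06), 10 (0.06) and 11 (0.07), of which chromosome 11 had not passed before (adjusted p = 0.17). Chromosomes 22 (-0.04, adjusted p = 0.25) and 17 (0.0059, adjusted p = 0.77) no longer passed. The permutation p-values take genes as the units and do not measure the spread between libraries. Corrected medians less the mean of the other libraries put KO replicate 1 at -0.035 on chromosome 11, within the WT libraries (-0.060 to -0.029). On chromosome 10 it lay at -0.0175, next to the WT range of -0.0475 to -0.021. Chromosome 20 followed 1 WT library. Its genes were higher in WT replicate 1 than in the mean of the other libraries by a median of 0.42 on the log2 scale after the correction (95% bootstrap interval 0.36 to 0.47), while the other 5 libraries lay between -0.10 and -0.06. Without WT replicate 1 the shift of chromosome 20 between the genotypes was -0.08 (adjusted p = 0.019). DNMT3B and RIMS4 lie on chromosome 20; in WT replicate 1 they stood at 1520 and 82.3 CPM, where the WT means were 1723 and 79.1 CPM.

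**Figure D4:**
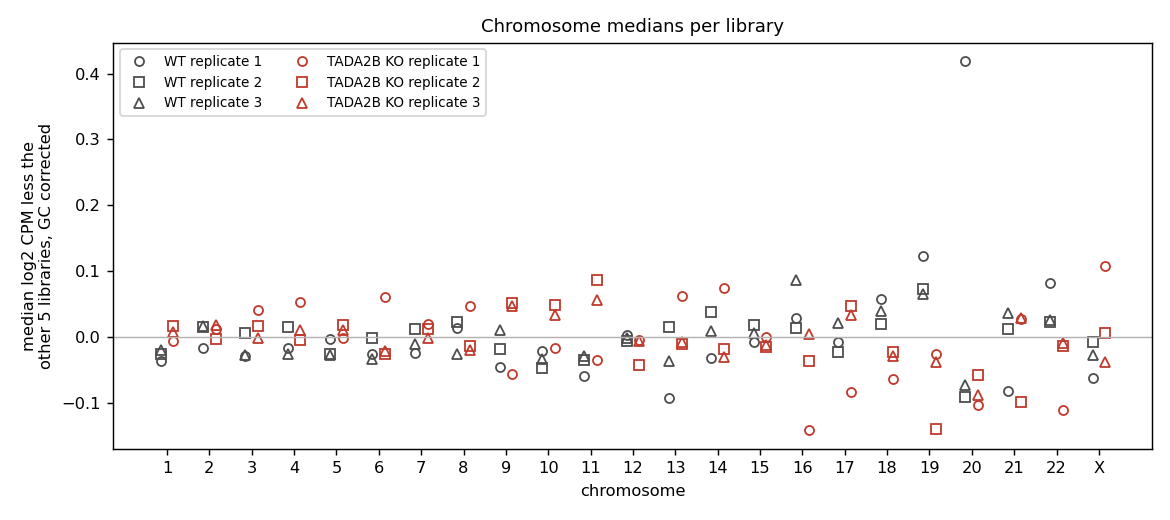
Median over the genes of each chromosome of log2 CPM less the mean of the other 5 libraries, after GC correction, for each library, WT in grey and TADA2B KO in red. WT replicate 1 lies at 0.42 on chromosome 20, and no other chromosome of any library is farther from 0 than 0.14.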

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

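The alternatives below were chosen before the data were examined unless said otherwise. The count of genes, 0 over all 6 libraries, depended on several of them. DESeq2 called 794 genes (462 higher, 332 lower, 627 by at least 2-fold), limma-voom 1 (lower, by at least 2-fold) and edgeR without the low-count filter 375 (254 higher, 121 lower, 375 by at least 2-fold), of which 338 had been tested before. Leaving out 1 library at a time gave 0 to 1017 genes, 0 to 588 higher, 0 to 429 lower and 0 to 953 by at least 2-fold, all above 0 only without KO replicate 1. Leaving out both libraries numbered 1, added after the data were seen, gave 2329 genes (1263 higher, 1066 lower, 1853 by at least 2-fold), 1012 of them shared with the 1017. Other scaling factors, the stricter filter, an adjusted p of 0.01, the GC correction and the removal of mitochondrially encoded genes (both added later) kept the count at 0. Fewer, more alike KO libraries were fitted without replicate 1; the cause of the other differences was not tested.

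The 12 lists became 0 with an estimated correlation and 0 with fry, and 13 to 20 when 1 library was left out (20 without WT replicate 1, 15 without KO replicate 1, of which 8 of the 12). TADA2B ran from -0.27 to 0.0066 when 1 library was left out, and was 0.067 without both libraries numbered 1. SOX2 ran from -0.48 to 0.43 and NANOG from -0.34 to 0.21 in the same way. SOX2 turned to -0.044 with limma-voom, -0.060 with the block, -0.012 without WT replicate 1, -0.48 without KO replicate 1 and -0.62 without both libraries numbered 1. NANOG turned to 0.21, 0.13 and 0.47 in the last 3 of these. The adjusted p stayed above 0.05 for both in each. The G2/M list lost its call without both libraries numbered 1, where its median was -0.017 and camera's direction turned (adjusted p = 0.90). The 15 chromosomes became 12 to 16 when 1 library was left out and 5 with the GC correction, 1 of which, chromosome 11, was new; chromosome 17 turned to 0.0059 there.

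With the replicate number as a block, 0 genes and 15 lists were called, 11 of them among the 12 called without it, and TADA2B stood at -0.12. Whether the numbers pair the samples cannot be settled with 3 libraries per group. Same-numbered libraries' deviations from their group means correlated at 0.11, -0.20 and 0.35. WT replicates 1 and 3 correlated best with the KO library of their own number, and WT replicate 2 with KO replicate 1. Depth limits genes of few reads: with 0 reads in KO and a floor of 3 reads over the group, C19orf81 and SHANK1 can only be said to be at least 24.2-fold and 20.4-fold lower.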

Other observations

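Tests chosen after the values were seen are those of the neuronal list, of the gene counts over other splits, of a WT library under a KO label, of the surrounding arm and all of chromosome 20; 3 of these, named below, took the place of an earlier test, and the tests of a chance placing and of GC content on chromosome 19 rest on 5 genes and a bound of -4 chosen after their values were seen.

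Many genes of neurons and synapses had lower estimates in KO, in a list written after such genes were seen among the largest differences. The list of 134 genes was written from general knowledge, without the neuronal genes named among the largest differences, and 111 were tested. Of these 83 lay below 0 and 28 above, with a median log2 fold change of -0.66, and 32 were lower and 4 higher at an unadjusted p under 0.05. Per library the median difference from WT was -0.38, -0.90 and -0.85 in KO replicates 1 to 3. The median was lower than in all 10000 random lists matched on mean expression (0 as low), and camera's unadjusted p was 5.57e-11 at the preset correlation and 0.028 with an estimated correlation. The latter was not adjusted with the 44 lists; the BMP targets, at a smaller unadjusted p of 0.019, had an adjusted p of 0.82 there, so no call is made for this list. After the GC correction the median was -0.49. That neuronal and synaptic genes move together in KO is a hypothesis, tested here by the matched random lists alone and on the data it came from. No gene of the list was called by edgeR over all 6 libraries, DESeq2 called 17, all lower, and edgeR without KO replicate 1 called 22 lower and 3 higher. Other single genes stood out too. CDKN2A, which encodes cell cycle inhibitors and is kept low in pluripotent cells, had 1.05, 37.6 and 13.1 CPM in KO against 0.48 ± 0.04 CPM in WT, and ZNF726 had 0 reads in all 3 KO libraries against 21, 56 and 60 in WT, at least 47.4-fold lower over the group.

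The 5 silent neighbours on chromosome 19 are a pattern that a chance placing of strongly lower genes does not give: with 11 genes below a log2 fold change of -4, 0 of 10000 random gene orders held a run of 5, and the longest was 2. A GC trend is argued against by a median of -6.96 after the GC correction. Loss of the surrounding arm on both copies is argued against by the nearest 20 tested genes, of which 18 keep at least 25% of the WT level in KO. This count took the place of an earlier test, the median of the same 20 genes (-0.656 less that of all genes), which lay near the bound set for a lost copy, so loss of 1 copy around the 5 genes is not excluded. A deletion on both copies and a silenced domain, either shared by all 3 KO libraries, stay open, as counts of RNA cannot part them; no biological explanation was tested. The 5 genes are not next to TADA2B, which lies on chromosome 4. Whether they follow from the loss of TADA2B or from a founder cell shared by the KO libraries cannot be told from these libraries.

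KO replicate 1 lay 0.90 from its nearest KO library (root mean square difference in log2 CPM), above the 0.73 of the farthest WT pair and the 0.51 between KO replicates 2 and 3, and it lay nearer to each WT library (0.85, 0.76 and 0.87). To test lower depth, mitochondrially encoded genes were left out and each library was thinned to the remaining depth of KO replicate 1. The distance was still 0.896, and that between KO replicates 2 and 3 was 0.519, which argues against lower depth alone. Leaving these genes out cannot test whether the state behind their high share changed the other RNA. A GC trend is argued against, with 0.896 after the GC correction. A mislabelled WT library is argued against by the longest run of neighbouring genes below a log2 fold change of -4, found again with KO replicate 1 left out. It was the same 5 chromosome 19 genes, and KO replicate 1 held 2 reads on them, where WT libraries held 338 to 491. The earlier test had chosen the 5 genes with KO replicate 1 included. A second test, run in between, decided less. It took genes with under 10% of the level of 2 WT libraries in KO replicates 2 and 3. Of these 19.4% to 31.2%, over the pairs of WT libraries, were as low in KO replicate 1, and 0% to 5.88% in the WT library left out, with exact 95% intervals that overlap (7.45% to 58.7% and 0% to 20.6%). The state of the culture, RNA quality and a difference between KO clones stay open; the mesenchymal genes high in KO replicates 2 and 3 may therefore belong to those cultures rather than to the loss of TADA2B.

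Chromosome 20 stood higher in WT replicate 1 by a median of 0.419 after the GC correction (0.477 before), which argues against a GC trend, and 0 of 10000 random gene sets of this size were as high. A few strongly changed genes are argued against by the lower quartile, which lay 0.476 above that of other genes (95% bootstrap interval 0.383 to 0.527); 51.1% of the chromosome's 315 genes were highest in this library, against 19.7% of other genes. That share was the first test, with a bound of 50%; it lay within counting error of the bound, and the quartile was chosen in its place. An extra copy of chromosome 20, a recurrent change of cultured pluripotent cells, may be behind this in part or all of the cells: both arms were higher, the short arm by 0.309 (0.192 to 0.390) and the long arm by 0.523 (0.411 to 0.596), where 3 copies over 2 would give 0.585. The intervals of the arms do not overlap, and that of the short arm lies below 0.585. This argues against an equal gain of both arms, though the intervals cover only the spread over genes in 1 library. Whether the long arm alone or mainly is gained was not tested.

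The count of 0 genes over all 6 libraries has its like in each of the 10 splits of the libraries into 3 and 3, with 0 as the highest other count. For lists, 7 of the 10 splits gave at least the 12 of the real one, and the highest other was 19. With 10 splits no share under 0.05 can be had. The split that sets WT replicates 1 and 2 with KO replicate 1 against the rest gave 2624 genes at an unadjusted p under 0.05, where the real one gave 2356.

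The lower medians of gene-dense chromosomes went with GC content. On chromosome 19 the 255 genes with a GC content below the median of all tested genes had a median of 0.0261 (95% bootstrap interval -0.0373 to 0.0634), less that of all genes, and the other 873 had -0.473; no explanation is weighed for these values.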
